A study of Mus musculus with 12 samples.

How the data were processed

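Gene expression was measured by RNA sequencing in 12 muscle samples of male mice in 4 groups of 3: wild-type sedentary, wild-type treadmill, NRF2-knockout sedentary and NRF2-knockout treadmill. Groups, replicate numbers, age and sequencing lanes were taken from the labels. Per the labels' protocols, libraries were made with Illumina's TruSeq RNA kit, version 2, which does not mark strand. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and the genome build GRCm38. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here.

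The authors deposited a table of raw counts per Ensembl gene, with 1 column per sample, and all tests rest on it. It holds 47729 genes, of which 47224 matched a gene symbol in the GENCODE annotation of GRCm38 used here; the unmatched genes hold 0.022% of counts. Coordinates come from that annotation. No genome sequence was used here, and shared sequence was searched in annotated transcripts alone.

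The authors also deposited a table of RPKM values for the same samples. Its values do not use each sample's own library total: the 12 totals run in turn down the table and on into the next column. With totals taken in that order the implied gene length was constant to within 0.1% in 3612 of 3612 well-counted genes, and with each sample's own total in 0 of them. Only 8.3% of the values carry their own total, and the others are scaled by 0.71 to 1.41. These RPKM values served as an alternative only, as deposited and rescaled to each library's own total.

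Total counts per library ranged from 21232040 to 29990968. Correlations of log2 CPM between libraries were 0.985 to 0.993. The lowest mean chi-square per gene between any pair of libraries was 6.9, where sampling noise alone gives 1, so no library was a copy of another.

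Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filter of filterByExpr (minimum count 10, minimum total 15), which kept 14194 genes and 99.94% of counts, and the quasi-likelihood test with 1 coefficient per group and 8 residual degrees of freedom. The common biological coefficient of variation was 0.112. P values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. A total of 7 comparisons were made: the treadmill effect in each genotype, the knockout effect in each exercise state, their interaction, and each effect averaged over the other factor. Values per group are mean CPM ± SD.

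A total of 43 gene lists were fixed (32 pathway lists and 11 lists of cell type markers), and the 39 with at least 3 measured members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over lists. Each was also tested with the correlation estimated per list and with fry. Too few members were measured for C57BL/6 substrain genes (2 of 3), neutrophil markers (2 of 10), lymphocyte markers (2 of 12) and keratinocyte markers (1 of 6). The count adjusted over the list alone applies Benjamini-Hochberg to the members of 1 list.

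The groups, the design, the lists, the rule for named genes and most alternatives were set before the data were examined. The rule names Nfe2l2 and 14 fixed genes always, and not every gene it names is described for every comparison. It adds the 10 genes that rose and the 10 that fell with the largest change among those past the threshold with a mean of at least 5 CPM in the higher group, a named symbol and no overlap between the libraries compared, or, in averaged comparisons, the same sign in both strata. It also adds up to 4 members of each list that passed or that counted at least 3 members past the threshold, or 2 by smallest p, given as values, where no member passed. For an interaction with no call it takes the 5 genes with the smallest p, and near Nfe2l2 up to 8 genes that passed. Other genes are said to be chosen after their values were seen, and 1 such gene is not reported here.

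The groups share replicate numbers. Deviations from the group means of same-numbered libraries correlated at 0.54, 0.30 and 0.26 between the wild-type groups, above 0.1 in every pair, so the numbers were taken to pair the wild-type libraries; these numbers coincide with lanes 7 and 8, lane 3 and lane 4. The main fit did not use this pairing. In the other comparisons at least 1 pair lay below 0.1.

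The tests were checked on simulated counts with the real genes' means and library sizes, 14194 genes and 3 simulations, with 100 genes changed per fold and libraries drawn independently, without pairing. For the treadmill effect in wild type the test recovered 43.7% at 1.5-fold and 74.0% at 2-fold, with 7.8% of calls false. For the averaged knockout effect it recovered 67.7% and 86.3%, with 5.7% false, and for the interaction 14.3% and 51.3%, with 4.8% false. Lanes were not simulated either, so recovery in the real libraries may differ.

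Alternatives were other normalizations (DESeq2's size factors, upper quartile), no filter and a stricter one (1 CPM in 6 libraries), DESeq2 1.42.0, limma-voom, limma-trend on log2(RPKM + 0.5), a replicate block, lane as a term with lanes 7 and 8 as 1 level, fits of only the 6 libraries compared, fits without lanes 7 and 8, and fits without each library in turn. For lists a prior count of 0.5 was tried, and for the region around Nfe2l2 windows of 10 and 40 Mb beside that of 20 Mb. Adjusted p values that DESeq2 left undefined were kept so. Other splits of the samples were counted, all 10 for groups of 3 and 100 drawn at random for the others. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.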

Results

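RNA sequencing was carried out on 12 muscle samples from male mice of a C57BL/6 background, all aged 5 months. The samples fell into 4 groups of 3: wild-type and NRF2-knockout animals, each either sedentary or exercised on a treadmill. NRF2, encoded by Nfe2l2, is a transcription factor that activates genes of antioxidant defence and detoxification. The labels do not say which muscle was taken, nor whether exercise was a single bout or a training programme. They give 3 samples per group without saying more about their origin, so p-values measure the spread between these samples. Total counts ranged from 21232040 to 29990968 per library, and 14194 genes passed the filter on low counts. Levels are given as CPM, each count scaled to the library total and normalization factor. Muscle of all 4 groups was dominated by fast-fibre transcripts. Myh4, the myosin heavy chain of the fastest fibres, had group means of 31266 to 35032 CPM, and Myh7, that of slow fibres, had 36.3 to 61.5 CPM; Myh4 was chosen after its values were seen.

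Libraries had been sequenced on 4 lanes, which the labels give. Lanes 3 and 4 held 5 libraries each, from both genotypes and both exercise states. Wild-type sedentary replicate 1 was on lane 7 and wild-type treadmill replicate 1 on lane 8, and these lanes held no knockout library. The first principal component (22.4% of variance) placed these 2 libraries at -31.1 and -28.3 and the other 10 between -2.6 and 13.9. In a fit with lane as a term, all 7 measured mitochondrially encoded mRNAs fell and 17 of 26 extracellular matrix genes and 12 of 16 macrophage and antigen presentation markers rose in lanes 7 and 8 relative to the others. By camera with a preset correlation the adjusted p values were 3.35e-06, 1.07e-09 and 5.09e-06; with an estimated correlation they were adjusted p = 0.462, 0.462 and 0.842.

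**Figure D1:**
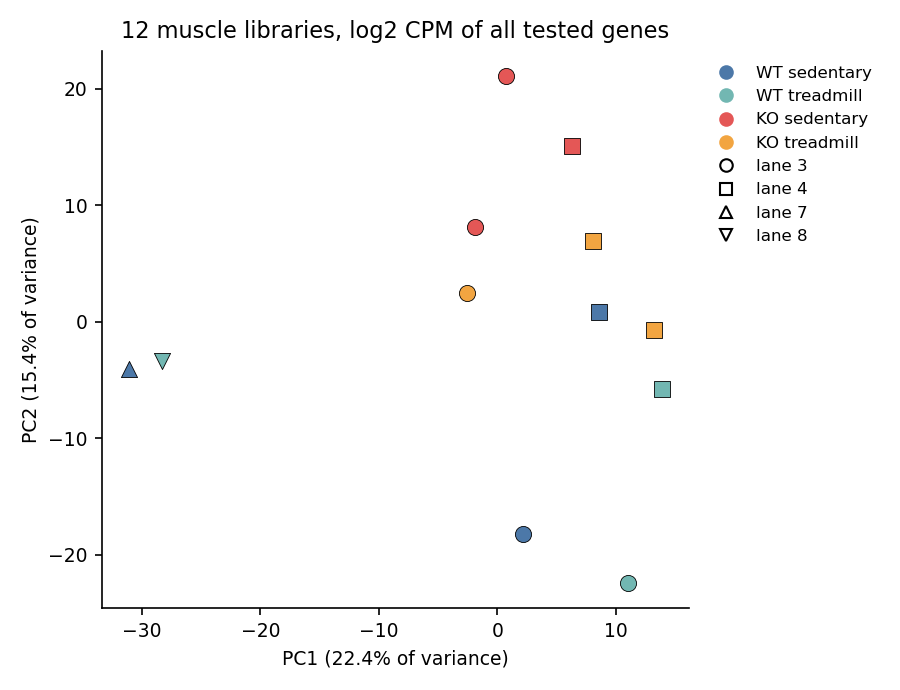
Principal components of log2 CPM for the 12 libraries, with PC1 (22.4% of variance) on the horizontal axis and PC2 (15.4%) on the vertical axis, coloured by group and shaped by sequencing lane. The libraries of lanes 7 and 8 sit at -31.1 and -28.3 on PC1, apart from the other 10.

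The targeted gene was examined first in every sample. Nfe2l2 lies on chromosome 2 at 75675513 to 75704641 (GRCm38, minus strand). It had 830 to 1275 counts in each of the 6 wild-type libraries and 54 to 84 in each of the 6 knockout libraries, so every library matched its genotype label. Its mean was 39.3 ± 2.2 CPM (SD, n = 3) in wild-type sedentary and 37.9 ± 3.4 CPM in wild-type treadmill muscle. In knockout muscle it was 2.29 ± 0.26 CPM in the sedentary and 2.89 ± 0.30 CPM in the treadmill group. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the transcript was 17.1-fold lower in sedentary knockout muscle (log2 fold change -4.10, SE 0.12, adjusted p = 4.23e-11) and 13.0-fold lower in treadmill knockout muscle (-3.71, SE 0.11, adjusted p = 1.17e-10). Within lane 3 and within lane 4 the log2 difference between genotypes was -4.06 and -3.78.

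The first comparison asked which transcripts depended on NRF2 in sedentary muscle. The genes that fell in the knockout included enzymes of detoxification and thiol redox control. Nqo1, a quinone reductase, went from 35.1 ± 6.7 to 9.69 ± 0.58 CPM (SD, n = 3 per group; log2 fold change -1.85, SE 0.15), and Aox1, an aldehyde oxidase, from 34.3 ± 1.6 to 10.1 ± 1.2 CPM (-1.76, SE 0.13). Osgin1, an oxidative stress-induced growth inhibitor, fell from 13.3 ± 1.3 to 3.29 ± 0.43 CPM. Srxn1, which repairs over-oxidised peroxiredoxins, fell from 26.6 ± 1.4 to 12.7 ± 0.58 CPM, and Txnrd1, the cytosolic thioredoxin reductase, from 73.8 ± 2.6 to 39.4 ± 1.6 CPM. Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, fell from 16.8 ± 1.5 to 10.9 ± 1.0 CPM. Outside this group Slc40a1, the iron exporter ferroportin, fell by 0.95 on the log2 scale, Pir by 1.38, Insyn1 by 1.32 and Creld1 by 0.91. Gclm, the modifier subunit of the same glutathione enzyme, did not pass (log2 fold change -0.30, adjusted p = 0.57), nor did Hmox1, which degrades haem (-0.53, adjusted p = 0.647). In the fit with lane as a term Gclm did pass, with a log2 fold change of -0.39 (adjusted p = 0.0253).

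In all, 27 genes passed in sedentary muscle, 2 higher and 25 lower in the knockout. The 2 that rose were Gys2, the liver form of glycogen synthase, from 0.77 ± 0.26 to 2.94 ± 0.68 CPM, and the unnamed gene Gm13943, from 2.21 ± 0.16 to 5.29 ± 0.52 CPM. Both fell outside the rule for named genes and were chosen after their values were seen. Of 32 measured NRF2 target genes 8 fell, 0 rose and 24 did not pass. Adjusted over the list alone, 15 fell and 1, Akr1b8, also chosen after its values were seen, rose. As a set the list was lower by camera (adjusted p = 9.27e-23, and adjusted p = 0.000174 with an estimated correlation). Interferon stimulated genes were higher as a set, with a median log2 fold change of 0.29 and 16 of 19 members above 0. None of them passed over all genes and 4 rose adjusted over the list alone, and the set's adjusted p = 6.63e-05 became adjusted p = 0.383 with an estimated correlation. The 8 tenocyte markers, genes of tendon cells, were all above 0 with a median of 0.30; 0 passed over all genes and 2 rose adjusted over the list alone (adjusted p = 0.000869, and adjusted p = 0.573 with an estimated correlation). The calls for Gclc and Slc40a1 were each lost without any 1 of several libraries. Gclc was lost without knockout sedentary replicate 2 or 3 or wild-type sedentary replicate 2, with adjusted p of 0.12 to 0.135. Slc40a1 was lost without any 1 of 5 libraries (adjusted p of 0.0641 to 0.221). Of these, knockout treadmill replicate 2 is not part of this comparison. The count of 27 became 16 without knockout sedentary replicate 2 or wild-type sedentary replicate 2, 81 with lane as a term (24 higher and 57 lower), 70 by DESeq2 and 323 without a filter on low counts.

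**Figure D2:**
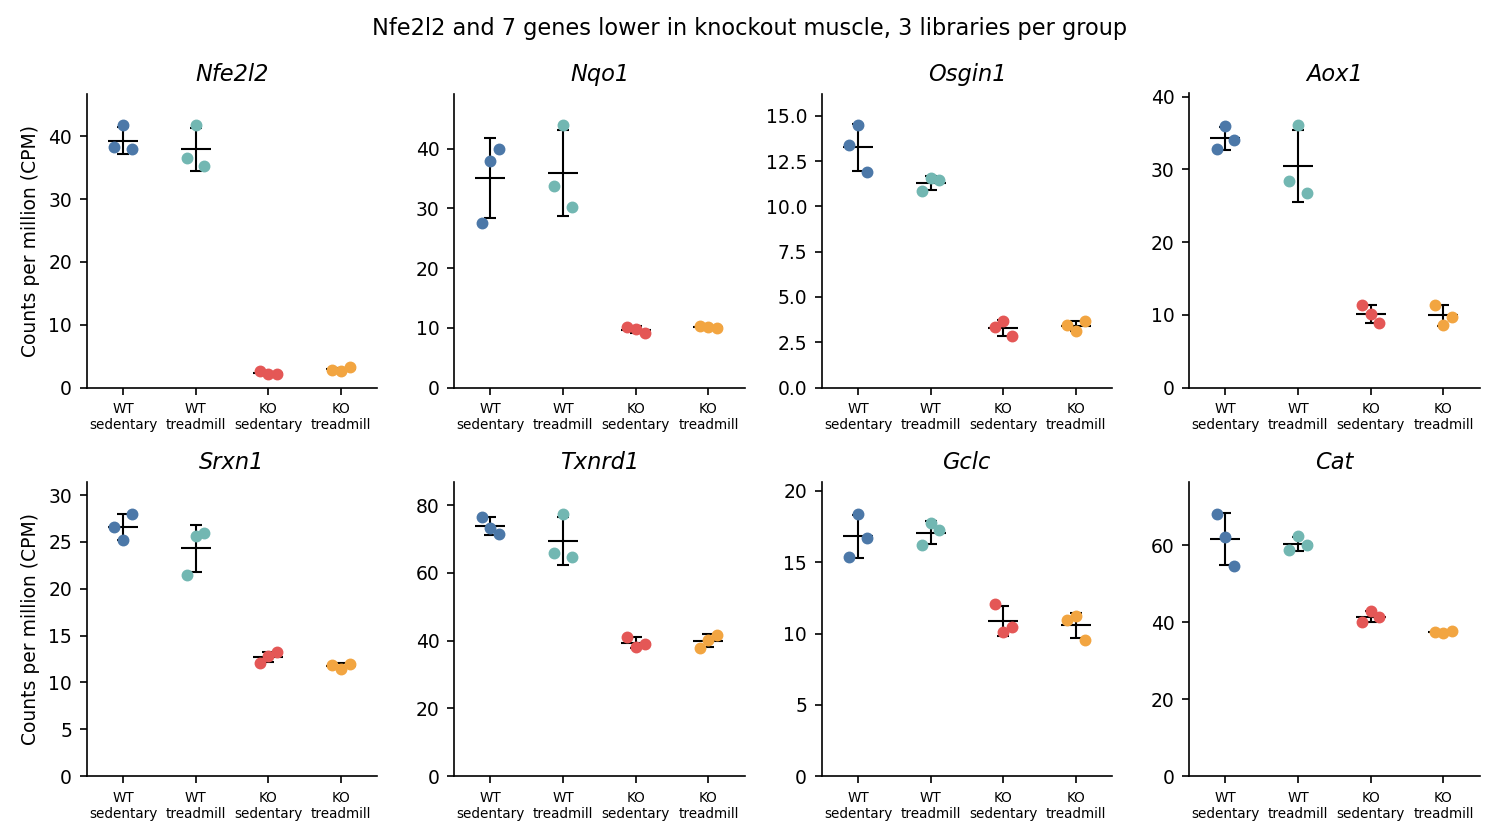
Levels (CPM) of Nfe2l2 and 7 genes lower in knockout muscle, in each of 3 libraries per group (points), with the group mean and SD (bars). For Nqo1 the wild-type groups averaged 35.1 and 35.9 CPM and the knockout groups 9.69 and 10.1 CPM.

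The same comparison in treadmill-exercised animals gave 23 genes, 1 higher and 22 lower in the knockout. Nqo1 averaged 35.9 ± 7.2 CPM in wild-type and 10.1 ± 0.17 CPM in knockout muscle (SD, n = 3 per group; log2 fold change -1.83, SE 0.15, adjusted p = 2.73e-05). Insyn1 fell again, Osgin1 fell by 1.72, Aox1 by 1.61, Srxn1 by 1.04, Creld1 by 0.88 and Txnrd1 by 0.80 on the log2 scale. Gclc averaged 17.1 ± 0.81 CPM in wild-type and 10.6 ± 0.88 CPM in knockout muscle. Pir and Htatip2 fell by 1.10 and 0.87, Vwa7 fell from 8.55 ± 1.0 to 4.28 ± 1.1 CPM, and Gys2 rose by 1.46. Exons of Vwa7 overlap a gene on the opposite strand, and the kit does not mark strand, so its counts are uncertain. Of the 32 measured NRF2 target genes 8 fell, 0 rose and 24 did not pass, and 15 fell adjusted over the list alone (camera adjusted p = 4.08e-23, and adjusted p = 0.000164 with an estimated correlation). Nuclear genes for subunits of oxidative phosphorylation were slightly lower as a set, with a median log2 fold change of -0.08 and 65 of 77 below 0. Of these genes 0 passed either way (camera adjusted p = 3.69e-06 for the set, and adjusted p = 0.907 with an estimated correlation). They averaged 7.48, 7.71 and 7.58 log2 CPM in knockout treadmill replicates 1 to 3 and 7.64, 7.70 and 7.71 in wild-type ones. Knockout treadmill replicate 1 thus weighed most. Erythroid markers, which follow the blood content of the tissue, were lower with a median of -0.62 and 6 of 6 below 0 (adjusted p = 0.000796, and adjusted p = 0.787 with an estimated correlation). Schwann cell and tenocyte markers had medians of 0.29 and 0.25 with 8 of 8 above 0 in each list (adjusted p = 0.00603 and 0.00841, and adjusted p = 0.787 for both with an estimated correlation). The calls for Pir and Vwa7 were lost without any 1 of several libraries, and that for Gclc without knockout treadmill replicate 3 (adjusted p = 0.072) or wild-type treadmill replicate 2 (adjusted p = 0.0542). The count of 23 became 15 without knockout treadmill replicate 2 or 3 or wild-type treadmill replicate 2, 37 without the libraries of lanes 7 and 8, 103 with lane as a term (45 higher and 58 lower), 52 by DESeq2 and 207 without a filter on low counts.

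The genes that passed overlapped between exercise states. The 2 comparisons share no library, and 18 genes were lower and 1 higher in both, where independent lists of these sizes would share 0.0387 and 0.000141. The wild-type libraries of the 2 states were taken to pair by number, which can make the 2 comparisons alike. Overlap or correlation expected under that pairing was not computed. A further 8 genes passed in sedentary and 4 in treadmill muscle without passing in the other. None of the 31 genes passed between states in the interaction test, whose smallest adjusted p among them was 1 and smallest unadjusted p 0.0174. That test recovered only 14.3% of genes simulated at 1.5-fold and 51.3% at 2-fold, so a difference between states could be missed. Across all 14194 genes the log2 fold changes of the 2 comparisons had a Pearson correlation of 0.364 and a Spearman correlation of 0.341, and 64.6% had the same sign; genes are not independent replicates. The Pearson correlation was 0.201 without wild-type sedentary replicate 1 and 0.205 without wild-type treadmill replicate 1, the libraries of lanes 7 and 8.

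**Figure D3:**
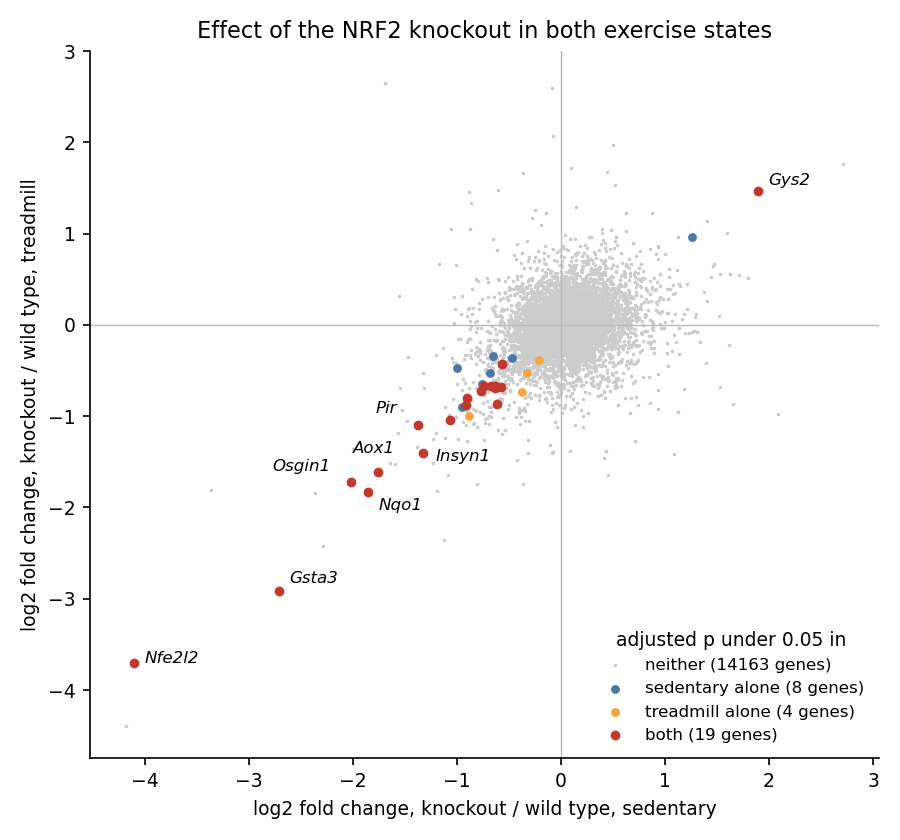
Log2 fold change of each gene between knockout and wild-type muscle in sedentary animals (horizontal axis) and treadmill-exercised animals (vertical axis), coloured by where its adjusted p was under 0.05. The 19 genes that passed in both states lie near the diagonal, with Nfe2l2 at -4.10 and -3.71.

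Averaged over the exercise states, 98 genes differed between genotypes, 18 higher and 80 lower in the knockout (n = 6 per genotype). Antioxidant enzymes beyond the NRF2 list moved in both directions. Catalase (Cat), which breaks down hydrogen peroxide, fell from 61.0 ± 4.5 to 39.4 ± 2.3 CPM, and Gpx4, which reduces lipid peroxides, fell by 0.28 on the log2 scale (SE 0.05). Gpx3, the extracellular glutathione peroxidase, rose from 184 ± 12 to 235 ± 21 CPM. Of 24 measured genes in that list 2 fell, 1 rose and 21 did not pass, with the same counts adjusted over the list alone. The set itself did not pass without lane, and was lower with lane as a term (adjusted p = 0.0307, and adjusted p = 0.466 with an estimated correlation). Among other genes that rose were Ostn, which encodes the secreted peptide musclin, from 98.7 ± 19 to 155 ± 16 CPM, the leptin receptor Lepr, from 5.12 ± 0.53 to 7.73 ± 1.0 CPM, and Sntb1, a syntrophin of the dystrophin complex, from 4.89 ± 1.1 to 8.14 ± 1.4 CPM. Bcl2, an inhibitor of apoptosis, fell from 16.0 ± 4.3 to 8.40 ± 2.0 CPM. Exons of Ostn and Bcl2 overlap a gene on the opposite strand, so their counts are uncertain.

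Of the 32 measured NRF2 target genes 12 fell, 0 rose and 20 did not pass in the averaged comparison, and 18 fell adjusted over the list alone. Beside those named above they included Gsta3 (log2 fold change -2.81), Gstm1 (-0.70), Gsr (-0.40), which regenerates reduced glutathione, Txn1 (-0.71) and Ftl1 (-0.71), the ferritin light chain, which the rule did not name and which were chosen after their values were seen. These glutathione transferases, Txn1 and Ftl1 have close copies in the genome, and exons of Ftl1 overlap a gene on the opposite strand, so their counts are uncertain. Txn1 had 40.4 and 42.5 CPM in the wild-type libraries of lanes 7 and 8, 24.1 to 27.5 CPM in the other 4 wild-type libraries and 17.4 to 20.1 CPM in the knockout, and Ftl1 was also higher in lanes 7 and 8 (log2 difference 0.62). With lane as a term Txn1 had a log2 fold change of -0.43 and Ftl1 of -0.47. The list's adjusted p by camera was 1.38e-25, and adjusted p = 0.000112 with an estimated correlation. Tenocyte markers were higher, with 1 of 8 rising over all genes, Thbs4 (log2 fold change 0.35, SE 0.07), and 4 adjusted over the list alone (adjusted p = 0.000425, and adjusted p = 0.67 with an estimated correlation). Interferon stimulated genes, heat shock genes, Schwann cell markers and oxidative phosphorylation subunits also passed with the preset correlation; with an estimated correlation their adjusted p = 0.886, 0.968, 0.968 and 0.979. Extracellular matrix genes, fibroblast markers and macrophage and antigen presentation markers were higher as sets in the knockout with lane as a term (adjusted p = 1.88e-08, 0.000203 and 0.000203), where without it they did not pass; with an estimated correlation they had adjusted p = 0.466, 0.466 and 0.627. Lane 3 alone gave 86 genes that differed by genotype, 41 higher and 45 lower, and lane 4 alone gave 49, 13 higher and 36 lower, from 3 knockout and 2 wild-type libraries each. The count of 98 ranged from 54 without knockout sedentary replicate 2 to 160 without wild-type sedentary replicate 3, and was 264 with lane as a term (115 higher and 149 lower), 233 by DESeq2 and 567 without a filter on low counts. Among the genes described in this comparison, the calls for Ostn, Sntb1, Bcl2, Gpx3, Gpx4 and Thbs4 were each lost without 1 or another library. Their adjusted p was then at most 0.107, while the calls for Cat and Lepr were not lost. The rule also named Tspan8, Tmem9, Ttc39b, Vit, Ubb, Tiam1 and Ptprd, which rose. The call for Tspan8 was not lost. Those for the other genes were lost without any 1 of 6 (Tmem9) to 11 libraries (Ptprd, adjusted p up to 0.149). Exons of Tspan8 and Ptprd overlap a gene on the opposite strand. Among the genes outside the rule, Txn1 was lost without any 1 of 7 libraries (adjusted p up to 0.0977) and Ftl1 without any 1 of 5 (up to 0.069), while Gsta3, Gstm1 and Gsr were not lost.

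Genes close to Nfe2l2 passed more often in this averaged comparison than those elsewhere. Within 20 Mb of Nfe2l2 on chromosome 2, 4 of 187 measured genes (2.14%) differed between genotypes, against 93 of 14006 others (0.664%; two-sided Fisher's exact test, odds ratio 3.27, 95% interval 0.863 to 8.8, p = 0.0393). They were E030042O20Rik at 75704770 to 75710024, next to Nfe2l2 (log2 fold change -1.68, SE 0.29), Osbpl6 (-0.33, SE 0.06), Gm13943 (1.11, SE 0.14) and the integrin subunit Itgb6 (-0.50, SE 0.10), with Itgb6 the farthest, at 60598292 to 60722643. By the same exact test the odds ratio was 2.45 without the adjacent gene (p = 0.132), 4.56 within 10 Mb (p = 0.0319) and 2.52 within 40 Mb (p = 0.0566). Cat lies 27.7 Mb away on the same chromosome.

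Treadmill exercise was then compared with the sedentary state in wild-type muscle. No gene passed by edgeR's quasi-likelihood test: 0 of 14194 had an adjusted p under 0.05, 308 had an unadjusted p under 0.05 where chance gives 710, and DESeq2 and limma-voom also gave 0. Without a filter on low counts 33 passed, and with the replicate number as a block in the 6 wild-type libraries alone, added after the data were seen, 1 passed. Ppargc1a, the coactivator of mitochondrial biogenesis, averaged 48.0 ± 5.6 CPM in sedentary and 48.9 ± 7.6 CPM in treadmill muscle (SD, n = 3 per group). Pdk4, which restrains glucose oxidation, averaged 620 ± 190 and 700 ± 180 CPM, and Nr4a3, an orphan nuclear receptor, 4.85 ± 2.0 and 2.70 ± 1.1 CPM. Of the other fixed genes, Ucp3 averaged 130 ± 37 and 137 ± 20 CPM, and Hk2 250 ± 68 and 225 ± 20 CPM. Tfam averaged 56.8 ± 3.1 and 63.1 ± 4.6 CPM, Sod2 202 ± 8.7 and 222 ± 17 CPM, and Nnt 45.8 ± 15 and 52.4 ± 3.5 CPM. Exons of Nnt overlap another gene entry of that name. Of the 32 measured NRF2 target genes 0 passed, over all genes or adjusted over the list alone, with a median log2 fold change of -0.01 and 15 above 0 (adjusted p = 0.532, and adjusted p = 0.677 with an estimated correlation). Among them Nqo1 had 0.03 (SE 0.14), Gclc 0.02 (SE 0.10), Txnrd1 -0.09 (SE 0.08), Srxn1 -0.13 (SE 0.09) and Gclm -0.20 (SE 0.11). On simulated counts of 14194 genes the test recovered 43.7% of genes changed 1.5-fold and 74.0% of those changed 2-fold in this comparison. The simulated libraries were independent, and neither they nor the test used the pairing of wild-type libraries by number. Since the real test gave 308 unadjusted p values under 0.05 where chance gives 710, these shares may overstate what it could detect.

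By camera with the preset correlation 17 of 39 lists passed in wild-type muscle, 10 higher and 7 lower in the treadmill group, and 0 passed with an estimated correlation, where the smallest was adjusted p = 0.677. No member of any list passed over all genes. Nuclear genes for oxidative phosphorylation subunits were slightly higher, with a median log2 fold change of 0.09 and 75 of 77 above 0 (adjusted p = 8.27e-09, and adjusted p = 0.677 with an estimated correlation); Cox6a2, the muscle form of a cytochrome oxidase subunit, had 0.26 (SE 0.10). Immediate early genes had a median of -0.27 with 22 of 24 below 0 (adjusted p = 5.16e-05, and adjusted p = 0.677 with an estimated correlation). Slow fibre genes had a median of -0.31 with 13 of 14 below 0 (adjusted p = 0.00272, and adjusted p = 0.677 with an estimated correlation), among them Myh7 at -0.76 (SE 0.25) and the slow calcium pump Atp2a2 at -0.45 (SE 0.14). Exons of Myh7, Atp2a2 and Cox6a2 overlap genes on the opposite strand, so their counts are uncertain, as are those of Gclm for the same reason. Adjusted over the list alone these 3 lists had 0 members that passed. Erythroid markers were higher in the same treadmill libraries, with 6 of 6 above 0, a median of 0.62 and 3 rising adjusted over the list alone (adjusted p = 6.51e-05, and adjusted p = 0.677 with an estimated correlation). Macrophage and antigen presentation markers had a median of -0.14 with 14 of 16 below 0 (adjusted p = 0.0243, and adjusted p = 0.687 with an estimated correlation), and turned direction without wild-type treadmill replicate 2 (adjusted p = 0.703). Of the 24 immediate early genes 12 were also higher in lanes 7 and 8, which hold 1 library of each wild-type group. In a fit with lane as a term and an estimated correlation, added after the data were seen, the immediate early list alone passed (adjusted p = 0.0311). In wild type the lane levels coincide with the replicate numbers taken to pair. By number this list averaged 3.20, 2.64 and 2.86 log2 CPM in sedentary and 2.87, 2.41 and 2.55 in treadmill libraries. The list tests without lane did not use that pairing, and no replicate block was run with an estimated correlation. The number of lists fell from 17 to 5 without wild-type sedentary replicate 1 and to 7 without wild-type treadmill replicate 2.

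**Figure D4:**
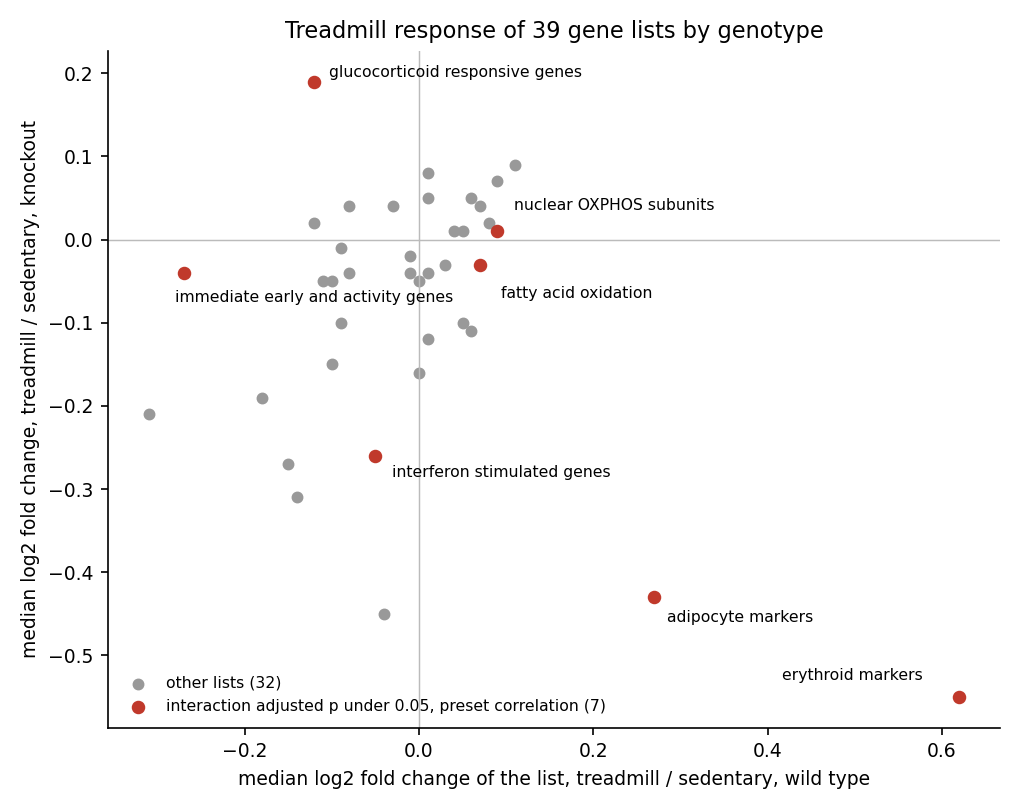
Median log2 fold change between treadmill and sedentary muscle of the 39 fixed gene lists in wild-type (horizontal axis) and knockout animals (vertical axis). The 7 lists coloured red differed between genotypes by camera with the preset correlation, such as erythroid markers at 0.62 and -0.55; none did with an estimated correlation.

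In knockout muscle the treadmill also gave 0 genes by edgeR's quasi-likelihood test, with 534 at an unadjusted p under 0.05 where chance gives 710, and 0 by DESeq2 and by limma-voom. A fit with lane as a term gave 26, and one without a filter on low counts 139. Ppargc1a averaged 52.8 ± 3.4 CPM in sedentary and 55.3 ± 11 CPM in treadmill muscle, and Pdk4 564 ± 69 and 670 ± 390 CPM (SD, n = 3 per group). By camera 11 lists passed, 4 higher and 7 lower, and 0 with an estimated correlation. Interferon stimulated genes had a median log2 fold change of -0.26 with 18 of 19 below 0; 0 passed over all genes and 1, Rsad2 (-0.61, SE 0.15), fell adjusted over the list alone (adjusted p = 5.75e-06, and adjusted p = 0.429 with an estimated correlation). Extracellular matrix genes had a median of -0.27 with 24 of 26 below 0 (adjusted p = 9.45e-05, and adjusted p = 0.694 with an estimated correlation), among them the proteoglycan Bgn at -0.42 (SE 0.17). Glucocorticoid responsive genes had a median of 0.19 with 14 of 15 above 0 (adjusted p = 0.0021, and adjusted p = 0.694 with an estimated correlation), among them Fkbp5, a co-chaperone of the glucocorticoid receptor, at 0.60 (SE 0.20). In those 2 lists 0 members passed, over all genes or adjusted over the list alone. Erythroid markers were lower in the same treadmill libraries, with 6 of 6 below 0 and a median of -0.55 (adjusted p = 0.00677, and adjusted p = 0.694 with an estimated correlation). So were macrophage and antigen presentation markers, with 14 of 16 below 0 and a median of -0.31 (adjusted p = 0.0138, and adjusted p = 0.851 with an estimated correlation), among them H2-Eb1 at -0.72 (SE 0.30). The number of lists was 7 without knockout sedentary replicate 3.

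The difference between genotypes in the response to the treadmill was tested as an interaction. It gave 0 genes by edgeR's quasi-likelihood test, with 270 at an unadjusted p under 0.05 where chance gives 710, and 0 by DESeq2 and by limma-voom, against 68 without a filter on low counts. The smallest p values, none passing, belonged to Cabyr (log2 difference -1.89, SE 0.44), Xlr3b (2.68, SE 0.65), Nim1k (-1.07, SE 0.26), Erg (-0.65, SE 0.16) and the mitochondrial arginine tRNA mt-Tr (SE 0.26, unadjusted p = 0.00196). Cabyr and Xlr3b lie near the floor, so their differences rest on few counts. Group means of Cabyr were 0.287 to 0.677 CPM. Xlr3b averaged 0.121 CPM in wild-type treadmill and 0.555 to 0.746 CPM in the other groups. Nqo1 had an interaction of 0.03 (SE 0.21) and Ppargc1a of 0.04 (SE 0.20). By camera 7 of 39 lists passed, 2 higher and 5 lower, and 0 with an estimated correlation, where the smallest was adjusted p = 0.642. Across genes the treadmill log2 fold changes in wild-type and knockout muscle had a Pearson correlation of 0.0691 and a Spearman correlation of 0.141, and 57.5% had the same sign. The Pearson correlation was -0.009 without wild-type sedentary replicate 1 and -0.038 without wild-type treadmill replicate 2. For the interaction the test recovered 14.3% of genes simulated at 1.5-fold and 51.3% at 2-fold, so changes of these sizes were often not detectable here. With 270 unadjusted p values under 0.05 in place of 710, even these shares may be too high for the real libraries.

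Averaged over genotypes, the treadmill gave 0 genes by edgeR's quasi-likelihood test, 589 at an unadjusted p under 0.05 where chance gives 710, 0 by DESeq2 and by limma-voom, 28 with lane as a term and 91 without a filter on low counts. By camera 16 lists passed, 7 higher and 9 lower, and 0 with an estimated correlation. Slow fibre genes had a median log2 fold change of -0.25 with 14 of 14 below 0, and 0 passed over all genes while 3 fell adjusted over the list alone (adjusted p = 0.000729, and adjusted p = 0.642 with an estimated correlation). These signs are those of the average, and a member can differ between genotypes. Myh7 averaged 61.5 CPM in sedentary and 36.3 CPM in treadmill wild-type muscle, but 45.7 and 59.9 CPM in knockout muscle. Fast fibre genes had a median of 0.09 with 14 of 15 above 0, and 0 passed either way (adjusted p = 0.00116, and adjusted p = 0.642 with an estimated correlation). Extracellular matrix genes had a median of -0.19 with 25 of 26 below 0, and 0 passed either way (adjusted p = 1.46e-05, and adjusted p = 0.642 with an estimated correlation). Satellite cell and regeneration genes had a median of -0.20, with 2 falling adjusted over the list alone (adjusted p = 0.00176, and adjusted p = 0.642 with an estimated correlation). Macrophage and antigen presentation markers were lower in the same libraries, with 15 of 16 below 0 and a median of -0.20 (adjusted p = 0.00166, and adjusted p = 0.642 with an estimated correlation). Within lane 3, 1 gene differed between treadmill and sedentary libraries, Alb, chosen after its values were seen; it had 19.9 CPM in knockout treadmill replicate 1 and 2.37 CPM in wild-type treadmill replicate 2, so that call rests on 1 library. Within lane 4, 10 genes passed, all lower in treadmill libraries; lanes 7 and 8 hold 1 library each. The number of lists fell from 16 to 9 without wild-type sedentary replicate 1. Slow fibre genes averaged 5.97 log2 CPM in wild-type sedentary replicate 3, a library that weighs on their fall. The other sedentary libraries had 5.05 to 5.72 and the treadmill libraries 5.11 to 5.61.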

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

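The list tests below were planned, and no test in this part was chosen after its result was seen. Each list is given because its treadmill response differed between genotypes by the interaction test with the preset correlation; none did with an estimated correlation. Erythroid markers had a median interaction of -1.17 on the log2 scale with 6 of 6 below 0 (adjusted p = 2.96e-07, and adjusted p = 0.642 with an estimated correlation). Their treadmill medians were 0.62 in wild-type and -0.55 in knockout muscle, 0 of 6 interactions passed over all genes and 5, all below 0, passed adjusted over the list alone, among them Alas2 (-1.25, SE 0.37), the first enzyme of haem synthesis in erythroid cells, whose exons overlap genes on the opposite strand. Erythroid transcripts made up 0.019% to 0.0474% of counts per library.

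Nuclear genes for oxidative phosphorylation subunits had a median interaction of -0.08 with 68 of 77 below 0 (adjusted p = 0.000337, and adjusted p = 0.956 with an estimated correlation). Interferon stimulated genes had a median of -0.22 with 19 of 19 below 0 (adjusted p = 0.000337, and adjusted p = 0.642 with an estimated correlation), with Isg15 at -0.97 (SE 0.36). Glucocorticoid responsive genes had a median of 0.32 with 15 of 15 above 0 (adjusted p = 0.000475, and adjusted p = 0.956 with an estimated correlation), with Glul, whose exons also overlap a gene on the opposite strand, at 0.56 (SE 0.30). Fatty acid oxidation genes had a median of -0.11 with 20 of 22 below 0 (adjusted p = 0.027, and adjusted p = 0.956 with an estimated correlation). Adipocyte markers had a median of -0.74 with 8 of 10 below 0 (adjusted p = 0.027, and adjusted p = 0.956 with an estimated correlation), with Fabp4 at -0.64 (SE 0.26). Immediate early genes had a median of 0.21 with 18 of 24 above 0 (adjusted p = 0.0306, and adjusted p = 0.956 with an estimated correlation). With lane as a term and the preset correlation, adipocyte markers (adjusted p = 0.244) and immediate early genes (adjusted p = 0.084) no longer passed, while the other 5 lists did. In these 6 lists 0 members passed, over all genes or adjusted over the list alone. Single libraries weigh on several of the lists. In knockout treadmill replicates 1 to 3 oxidative phosphorylation genes averaged 7.48, 7.71 and 7.58 log2 CPM, and fatty acid oxidation genes 6.39, 6.61 and 6.72. Glucocorticoid responsive genes averaged 5.94, 5.33 and 5.05 in wild-type sedentary replicates 1 to 3, and 11 of 15 were higher in lanes 7 and 8. Adipocyte markers averaged 3.80, 4.98 and 3.71 log2 CPM in knockout sedentary replicates 1 to 3, and 4.07, 4.22 and 3.31 in the knockout treadmill replicates. Without sedentary replicate 2 the sedentary values lie within the treadmill range, so the knockout side of that result rests largely on 1 library. No test for samples far from others in their group was run, since each group holds 3.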

How the results depend on the processing

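Alternatives chosen after the data were seen were the rescaled RPKM, the replicate block in the wild-type libraries alone, the lane term with an estimated correlation, and the count near Nfe2l2 without its adjacent gene. Where a value moved below, the cause was not tested unless the setting shows it. The NRF2 target list was lower under each alternative run on lists, with a largest adjusted p of 0.00134 in sedentary animals, 0.00205 in treadmill animals and 0.00113 averaged. Lane and replicate block were not fitted together, since lanes 7 and 8 hold only replicate 1 of the wild-type groups.

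Counts are given for the treadmill effect in wild type and knockout, the knockout effect in sedentary and treadmill animals, the interaction, and the averaged treadmill and knockout effects, which were 0, 0, 27, 23, 0, 0 and 98. Without a filter on low counts they were 33, 139, 323, 207, 68, 91 and 567. With lane as a term they were 0, 26, 81, 103, 0, 28 and 264, with 24, 45 and 115 of the knockout calls higher, and 27 of 27, 23 of 23 and 95 of 98 knockout calls were kept. DESeq2 gave 0, 0, 70, 52, 0, 0 and 233, and limma-voom 0, 0, 27, 23, 0, 0 and 99. Without the libraries of lanes 7 and 8 the knockout counts were 35, 37 and 158, with 0 elsewhere. The deposited RPKM gave 5, 4 and 18 for the knockout effects and 0 elsewhere, with a known defect of scale; rescaled, they gave 28, 22 and 73. Fits of only the 6 libraries compared, which have fewer degrees of freedom, gave 16 in sedentary and 19 in treadmill animals.

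The replicate block gave 0, 0, 42, 40, 0, 0 and 217. Same-numbered libraries correlated at 0.17, 0.08 and 0.22 for the treadmill effect in knockout, at 0.05, -0.10 and 0.07 for the knockout effect in sedentary and at 0.28, 0.01 and 0.22 in treadmill animals, so the numbers were not taken to pair those libraries. Each library correlated best with its own number for the treadmill effect in both genotypes, but not for the knockout effects. In wild type, where the numbers were taken to pair, a block in those 6 libraries alone gave 1 gene. In wild type the block in all 12 libraries also ended the calls of heat shock genes (adjusted p = 0.0534) and proteasome subunits (0.0541), each 0.0491 without it, and changed no other call there.

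Without each library in turn the 4 treadmill and interaction counts stayed at 0. The knockout count in sedentary animals ranged from 16, without knockout or wild-type sedentary replicate 2, to 36. In treadmill animals it ranged from 15, without knockout treadmill replicate 2 or 3 or wild-type treadmill replicate 2, to 30. Averaged, it ranged from 54, without knockout sedentary replicate 2, to 160, without wild-type sedentary replicate 3; without any other knockout library it was 58 to 65, and it was 64 without wild-type sedentary replicate 2 and 61 without wild-type treadmill replicate 2.

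List counts with the preset correlation were 17, 11, 3, 6, 7, 16 and 6. With an estimated correlation and with fry they were 0, 0, 1, 1, 0, 0 and 1, and with lane and an estimated correlation 1, 0, 1, 1, 0, 0 and 1. The replicate block gave 5 lists for the knockout in sedentary animals. With lane as a term the knockout list counts were 8, 17 and 15. Extracellular matrix, fibroblast and macrophage lists were higher in all 3 (adjusted p = 8.7e-09, 0.00517 and 0.0019 in sedentary and 0.000198, 0.00133 and 0.00363 in treadmill animals). Other antioxidant enzymes were lower in treadmill animals (0.00968). All these calls were lost with an estimated correlation, and the wild-type libraries of lane 3 weigh on the matrix and macrophage lists. Without lanes 7 and 8 the knockout list counts were 11, 15 and 14, with 11 for the interaction. Without each library in turn the list counts of all comparisons ranged from 5 to 18, 7 to 15, 3 to 11, 4 to 14, 5 to 11, 9 to 18 and 2 to 10. In wild type they were 5 without sedentary replicate 1, 7 without treadmill replicate 2 and 10 without replicate 3 of either group; the lowest of the others came without knockout sedentary replicate 3 (7), wild-type sedentary replicate 1 (9) and knockout treadmill replicate 1 (2). For the knockout in sedentary animals they were 11 and 6 without knockout sedentary replicates 1 and 2, 9, 7 and 8 without wild-type sedentary replicates 1, 2 and 3, and 8 without wild-type treadmill replicate 3. Without wild-type treadmill replicate 1 they were 14 in treadmill animals, 11 for the interaction and 10 for the averaged knockout effect. List directions turned in 4 cases: mitochondrially encoded mRNAs (adjusted p = 0.482) and proteasome subunits (0.612) in wild type without sedentary replicate 1, macrophage and antigen presentation markers (0.703) without treadmill replicate 2, and lipogenesis (0.83) in knockout without sedentary replicate 2. Their leave-one-out ranges were 0.00128 to 0.543, 0.00912 to 0.612, 7.9e-11 to 0.703 and 0.000121 to 0.83.

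The correlation of treadmill effects between genotypes ranged from -0.038 to 0.149 without each library in turn, below 0 without wild-type sedentary replicate 1 (-0.009) and wild-type treadmill replicate 2 (-0.038). That of knockout effects between exercise states ranged from 0.201 to 0.417. Over the genes called in either state, Nfe2l2 among them, it was 0.98. Those genes were picked by passing in these same comparisons, which favours a high value, so the 0.98 is no separate evidence. The odds ratio near Nfe2l2 was 4.56 within 10 Mb, 2.52 within 40 Mb and 2.45 without the adjacent gene. Of 49 values of named genes past the threshold, 33 were lost with the deposited RPKM, 10 with rescaled RPKM, 3 to 13 without 1 library and 0 with DESeq2, limma-voom, lane or block; 63 of 218 named values that did not pass changed sign in some setting. At 21232040 to 29990968 counts per library 14194 of 47729 genes passed the filter, and changes in the rest were not tested under it.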

Other observations

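In this part the test of shared sequence for lanes 7 and 8, that for genes with a large lane difference, whose bound of 1.5 was set with those genes in view, that of mitochondrial mRNAs without mt-Atp8, the liver test without Alb and the test near Nfe2l2 without the adjacent gene were chosen after the results they concern were seen. The genes named in this and the next paragraph were chosen after their values were seen. In the averaged comparison of genotypes Gbe1, the glycogen branching enzyme, fell by 0.60 (SE 0.07), Phka1, a muscle subunit of phosphorylase kinase, by 0.50 (SE 0.07), and Gaa, which degrades glycogen in lysosomes, by 0.41 on the log2 scale, a call lost without any 1 of 11 libraries (adjusted p up to 0.112), while Gys2 rose by 1.68 (SE 0.18); Gaa and Gys2 are not on the fixed list of glycolysis and glycogen genes. Of the 24 genes of the glycolysis and glycogen list 2 fell, 0 rose and 22 did not pass, and 3 fell and 2 rose adjusted over the list alone. The list did not pass as a set (adjusted p = 0.42, and adjusted p = 0.979 with an estimated correlation). Among 22 regulators of mitochondrial biogenesis 1 fell, the nuclear receptor Esrra (log2 fold change -0.30, SE 0.05), and 3 fell adjusted over the list alone. Mafg, which encodes a DNA-binding partner of NRF2, fell by 0.42 and Bach1, which encodes a repressor at the same sites, by 0.50. Exons of Esrra and Mafg overlap other genes, so their counts are uncertain.

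The treadmill was also compared within lanes. Within lane 4, from 3 treadmill and 2 sedentary libraries, 10 genes fell. They included the antigen presentation genes Cd74 (-0.78), H2-Aa (-0.80) and H2-Eb1 (-0.91), the myeloid genes Mpeg1 (-1.07) and Ccr2 (-0.98), the matrix genes Postn (-1.11), Cilp (-0.63) and Aspn (-0.56), Csrp3 (-0.62) and Egr1 (-1.07). Within lane 3, 1 gene passed, Alb at 3.54, which was high in 1 of the 2 treadmill libraries there. With lane as a term in all 12 libraries 0 of those 10 lane 4 genes passed in any treadmill comparison. That fit gave 26 genes for the treadmill in knockout, 8 higher and 18 lower. The largest changes were those of the liver transcripts Serpina3k (3.33) and Apoa2 (3.20), and genes that fell included Ankrd2 (-0.74), Fabp3 (-0.66) and Atf3 (-0.75). Exons of Aspn, Fabp3 and Serpina3k overlap other genes.

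Other splits of the samples were counted for each comparison. For the averaged knockout effect 2 of 100 splits, the real one included, gave as many genes as the real 98, and the highest other gave 125. That share is under the 0.05 set beforehand as arguing against chance. The split count alone cannot separate genotype from lane, since the real split keeps the libraries of lanes 7 and 8 on the wild-type side. The other split put all 5 lane 4 libraries and 1 lane 3 library on the same side. Lane 3 alone gave 86 genes (41 higher) and lane 4 alone 49 (13 higher) for the knockout. Each fit rests on only 5 libraries, which are also part of the main fit. The wild-type libraries of lane 3 stood apart on the second principal component, at -18.2 and -22.4, where the others lay between -5.8 and 21.1. For the knockout effect in sedentary animals 1 of 10 splits gave as many as 27, with a highest other of 0, and in treadmill animals 1 of 10 gave as many as 23, with a highest other of 0; 10 splits are too few for a share under 0.05. For the treadmill effect the real count was 0 in both genotypes, which 10 of 10 splits reach by necessity, so these splits decide nothing and are also too few; the highest other was 176 in wild type and 2 in knockout. The split with 176 genes put the libraries of lanes 7 and 8 together, which points to a structure of the samples. For the interaction and the averaged treadmill effect the real count was 0 as well, so 100 of 100 splits reach it by necessity and the comparison says nothing about chance. The highest other gave 77 in each, from splits that put the libraries of lanes 7 and 8 together.

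The libraries of lanes 7 and 8 stood apart from the other 10, with 1339 genes higher and 1348 lower. Depth alone is argued against, since 102.2% of the gap on the first principal component was left after thinning every library to the smallest library total, 21232040 counts, and gene length is too, with a Spearman correlation of -0.049 across genes. Shared sequence does not account for the whole either, since genes sharing at least 50% of their 50-base words with others differed no more often than genes sharing none (18.1% against 19.4%, odds ratio 0.916, 95% interval 0.729 to 1.14), but among 59 genes with a log2 difference above 1.5 it was more frequent than elsewhere (27.1% against 4.01%, odds ratio 8.91), as in Rps7, with 30.4 and 34.4 CPM in those libraries and 0.43 to 0.94 CPM in the rest. The difference followed GC content, with a Spearman correlation of 0.494 across genes, and a candidate explanation is a difference in library preparation, sequencing or read handling between runs. Tissue differences between those animals stay open and untested; extracellular matrix and macrophage genes moved with the lanes.

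Calls near Nfe2l2 were more frequent than elsewhere, with an odds ratio of 3.27 within 20 Mb (Fisher's exact test, 95% interval 0.863 to 8.8, p = 0.0393). This would follow from DNA of another strain carried along with the targeted locus, which may differ in sequence or expression from C57BL/6. Without E030042O20Rik, which starts next to Nfe2l2, the odds ratio was 2.45 (exact 95% interval 0.492 to 7.5, p = 0.132), so the excess rests partly on a gene that the targeting itself could alter. With lane as a term it was 3.76 by the same exact test (p = 0.000193). Regulation of these genes by NRF2 stays open and was not tested.

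Of the 13 mitochondrially encoded mRNAs, mt-Co2, mt-Atp8, mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l had 0 to 2 counts over all 12 libraries, against 16374207 for mt-Co1. Without mt-Atp8 the lowest share of 50-base words found in a nuclear transcript was 98.0%, all with pseudogenes on chromosome 1 between 24612407 and 24615565, which is consistent with loss of reads that match both places. For mt-Atp8 the share was 0.0%, below the 50% set beforehand as arguing against this. That bound was wrong for this gene because annotated transcripts alone were searched: the pseudogenes of its neighbours leave an unannotated gap of 233 bases at 24614652 to 24614884, and mt-Atp8 has 204 bases. The gap was not searched, since no genome sequence was used here, and no biological explanation was tested.

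A transfer of liver RNA into single libraries was tested as a hypothesis, since Alb had 19.9 CPM in knockout treadmill replicate 1 and 0.70 to 2.50 CPM in the other libraries. The 9 measured liver genes had a median log2 ratio of 0.41 there, and without Alb, by which the library was picked, 0.40 with 8 of 8 above the median of the others; that check was added after the first value was seen. Both values are below the 0.5 set beforehand as arguing against liver RNA, and wild-type treadmill replicate 2 had 0.41 without Alb, with 5 of 8 above. Only 9 of 25 listed genes (36%) were measured in this muscle, too few for the check to decide. That limit was applied after the value was seen. Some of the 9 were also well above the floor in every library, such as Cyp2e1 (20 to 52.5 CPM) and Hp (14.2 to 35.4 CPM). A small addition of liver RNA could leave the median ratio below 0.5, so liver RNA in that library may still be present. Serpina3k had 2.34 CPM in it and 0.03 to 1.0 CPM elsewhere, and Apoa2 1.29 CPM and 0.0739 to 0.592 CPM elsewhere, while Cyp2e1 had 45.7 CPM and Hp 27.2 CPM in it, and 52.5 and 35.4 CPM in wild-type treadmill replicate 2.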
